A study of Bos taurus with 79 samples.

How the data were processed

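Endometrium of cross-bred beef heifers was profiled on Affymetrix bovine arrays, with 1 array for each of 79 samples. Per the labels, total RNA was extracted with Trizol from strips of endometrium, treated with DNase on a column, cleaned and made into biotin-labelled cRNA. The labels place each sample in 1 of 16 groups by day (5, 7, 13 or 16), status (cyclic or pregnant) and progesterone (normal or high). Each group held 5 arrays, except cyclic heifers with high progesterone on day 7, of which 4 arrays were deposited, so that arm of 4 rested on fewer animals.

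The deposited values are log2 expression values per probe set, ranging from 0.95 to 15.37. Per the submitters' processing notes RMA, GCRMA and limma were used, without versions, and the notes do not state which of the first pair made the deposited values, so the background correction behind low values is unknown. All arrays had medians between 4.71 and 5.12 and standard deviations between 2.60 and 2.93. The median mean level of a probe set was 5.04, and 32.2% of probe sets had a mean under 3, a range in which changes are compressed. The number of arrays limits the precision of every value.

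Of the 24128 probe sets 112 Affymetrix controls were left out, since they do not measure bovine genes, which left 24016 without a filter on level. Gene symbols came from the platform annotation: 13292 probe sets had 1 symbol, 86 had several and 10638 were treated as unnamed. The gene identifiers of 13263 probe sets were found in a current cattle gene table, which changed 0 symbols and was used for names only, so no positions are given. These probe sets represented 9155 named genes, of which 2913 had several probe sets, and a gene was represented by its probe set with the highest mean.

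Group means of the deposited values were fitted with limma 3.58.1 (statmod 1.5.0) in R 4.3.3 over all 79 arrays, with empirical Bayes moderation without trend or robust options, on 63 residual degrees of freedom and 1.49 prior degrees of freedom. From this fit 16 comparisons were drawn: the effect of pregnancy and the effect of progesterone on each day, each averaged over the levels of the other factor, their interaction on each day, the changes between successive days in cyclic heifers with normal progesterone, and the change of the pregnancy effect from day 13 to day 16. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were counted as changed, and all adjusted p values of single genes come from limma. Replicate numbers were not treated as pairs, since arrays of the same number were not alike: their deviations from group means had mean correlations of 0.0294, 0.0467, 0.0228 and -0.00919 on days 5, 7, 13 and 16.

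An advance of the cycle was tested by the Spearman correlation, across probe sets that changed over time, of the progesterone difference in pregnant heifers with the change to the next day studied in cyclic heifers. It was assessed two-sided by exact permutation over all relabellings of the 5 arrays of each group and adjusted over 3 tests. In addition 28 lists of pathways and cell type markers, with 796 symbols written and 589 genes measured, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and with an estimated correlation and fry beside it. Members past the threshold were counted over all probe sets and adjusted over the list alone. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 served for annotation and plots.

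Named genes followed a rule. It took the 8 highest and 8 lowest changes among genes past the threshold with a proper symbol, with the same sign in both arms of the average for pregnancy and progesterone, and up to 3 members past the threshold from each list. It always admitted PGR, ESR1 and OXTR, also ISG15, MX1 and MX2 for pregnancy, and DKK1, DGAT2, MSTN, LTF, MEP1B and ANPEP for progesterone and days. A further gene of the rule is not reported here. The text names part of the genes so admitted, and any other gene is marked as chosen after its values were seen. The comparisons, tests, threshold, lists, this rule and the alternatives were fixed before the data were examined, apart from the alternatives named next as later.

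The alternatives were a fit of the days concerned only, quantile normalization or median centring of the deposited values, probe sets above the median level only, trend and robust moderation, array weights, a replicate block, each arm of an average alone, pregnant heifers for the changes over days, and the omission of each array in turn. Omissions of 2 arrays with a narrow distribution (SD under 2.7), of 5 arrays far from their group mean (SD of deviations over 0.45) and of 3 arrays with high smooth muscle markers (mean over 10) were added later, after the data were seen. For each comparison 100 splits of the same arrays into groups of the same sizes, the real one included, were counted.

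The fit was tested on simulated data of the same size, 24016 probe sets with 50 changed at each of 4 sizes. Of changes of 1 log2 unit it recovered 88% for pregnancy on day 16, 86% for progesterone on day 7, 92% for day 7 against day 5 and 56% for the interaction on day 16, with 5 of 183, 11 of 184, 5 of 170 and 9 of 142 calls false. The simulated probe sets were normal and independent of each other, with the same spread in all groups and no floor or deviant arrays. Real arrays differ in this, so these shares are not error rates of the real counts. The best correlation between any pair of arrays was 0.9932, and no pair of arrays held the same values.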

Results

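Gene expression was measured in the endometrium of cross-bred beef heifers on 79 Affymetrix bovine arrays, 1 array per sample. The heifers were cyclic or pregnant, had a normal or a high progesterone concentration, and were slaughtered on day 5, 7, 13 or 16 after estrus. High progesterone came from an intravaginal releasing device put in place on day 3 and kept there until slaughter. Groups are called CN (cyclic, normal progesterone), CH (cyclic, high), PN (pregnant, normal) and PH (pregnant, high), and an array is named by its group and replicate number, as in CN 2. Each of the 16 groups held 5 arrays, except CH on day 7, which held 4. The deposited log2 values ran from 0.95 to 15.37, array medians from 4.71 to 5.12, and 24016 probe sets were tested, which represented 9155 named genes. The number of arrays per group limits the precision of every value. Differences are given on the log2 scale ± SE of the fit, and group levels as mean log2 ± SD. That SE uses 1 spread per probe set shared by all 16 groups, so it and its p can be too small where the groups compared vary more. Where a group lay near the floor of the values, at a mean under 3, the difference is a lower limit of the change. This does not hold for interactions and other differences of differences, which the floor can make too small or too large.

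The course of the cycle was asked first, in CN heifers (n = 5 on each day). From day 7 to day 13 IGFBP1 (gene ID 282259), a binding protein of insulin-like growth factors, rose by 6.80 ± 0.47, from 2.92 ± 0.04 near the floor to 9.72 ± 1.54, with every day 13 array above every day 7 array. This difference is a lower limit. SLC39A2, a zinc transporter, rose by 7.45 ± 0.63, MEP1B, a subunit of the meprin protease, by 5.49 ± 0.44, PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, by 5.23 ± 0.59, and SLC5A1, the sodium-coupled glucose transporter, by 4.41 ± 0.47. UPK1B (gene ID 282113), a uroplakin of the epithelial surface, fell by 8.43 ± 0.52, from 11.11 ± 0.61 to 2.68 ± 0.61, near the floor and so also a lower limit. ANPEP, an aminopeptidase, fell by 5.39 ± 0.50, SLC2A5, the fructose transporter, by 5.18 ± 0.93, and ELOVL7, a fatty acid elongase, by 4.22 ± 0.37. Adjusted p for these 9 genes lay between 4.61e-20 and 2.12e-05. In all, 3898 probe sets changed, 1932 upward and 1966 downward, and 686 and 651 of these changed at least 2-fold.

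Cell cycle genes fell together from day 7 to day 13: 24 of the 38 measured members fell and none rose, against 29 that fell and 1 that rose when adjusted over the list alone. The mean of the list went from 5.99 ± 1.09 to 4.39 ± 0.06. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, changed by -4.18 ± 0.61, NUSAP1, a spindle protein, by -3.60 ± 0.53 and BIRC5, the chromosomal passenger protein survivin, by -3.54 ± 0.60. The camera test of the list gave adjusted p = 3.01e-11, and adjusted p = 0.8 with an estimated correlation. Of the 41 histotroph and progesterone-response genes, which code largely for secreted proteins, transporters and proteases, 16 rose and 6 fell (17 and 7 adjusted over the list alone; camera adjusted p = 0.000771, and adjusted p = 0.151 with an estimated correlation). That list was drawn partly from published work on these animals, so it is not independent evidence of its direction. DKK1, a secreted Wnt antagonist, rose by 2.75 ± 0.68, whereas LTF, the iron-binding protein lactoferrin, changed by -3.22 ± 0.77. Among 15 epithelial markers 3 rose and 1 fell, with the tight junction genes CLDN4 at 3.04 ± 0.37 and CLDN10 at -2.66 ± 0.59. PGR, the progesterone receptor, changed by -0.88 ± 0.30 (adjusted p = 0.0356) at a mean level of 2.78, near the floor of the values. It lost this call without CN 2 or CN 5 of day 7 or CN 1, CN 2 or CN 4 of day 13.

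Between day 5 and day 7 of the cycle 7 probe sets passed the threshold, 3 higher and 4 lower, and 1891 had an unadjusted p under 0.05. The 2 named genes among them were DPT, the matrix protein dermatopontin, at -2.88 ± 0.61, and MCMBP, a binding protein of the replicative helicase, at 1.15 ± 0.24 (adjusted p = 0.0429 for each, n = 5 per day). Each lost its call in 8 of the 10 omissions of 1 array, the exceptions being CN 1 of day 5 and CN 5 of day 7. In PN heifers 1155 probe sets changed over the same days, but the difference between these courses passed the threshold for 0 probe sets by limma, with 1664 at an unadjusted p under 0.05. The count was 596 without CN 5 of day 7 and 154 without CN 1 of day 5. It fell to 1 without CN 4 of day 5 or CN 1 or CN 3 of day 7, to 3 without CN 4 of day 7 and to 4 without CN 5 of day 5 or CN 2 of day 7. It was 881 without the 5 arrays farthest from their group mean, 1386 with array weights, 4 with a replicate block, 1 in a fit of these days alone and 0 among the brighter probe sets.

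From day 13 to day 16 CRYGS (gene ID 281724), a crystallin, rose by 5.80 ± 0.75, from 2.94 ± 1.36 to 8.74 ± 1.05 (adjusted p = 8.69e-07, n = 5 per day, all day 16 arrays above all day 13 arrays). On day 13 4 of its 5 arrays lay under 3, so the difference is a lower limit. DPP4, a cell surface dipeptidase, rose by 2.29 ± 0.47, SLC2A1, the facilitative glucose transporter, by 1.39 ± 0.27 and ITGB3, an integrin subunit, by 1.29 ± 0.29. PDZK1IP1, a membrane-associated protein, changed by -3.15 ± 0.64, CRIPTO, a co-receptor of the Nodal pathway, by -2.80 ± 0.62, DGAT2 (gene ID 404129), an enzyme of triglyceride synthesis, by -2.62 ± 0.62 and PSAT1, an enzyme of serine synthesis, by -2.39 ± 0.36. OXTR (gene ID 281371), the oxytocin receptor, differed by 2.92 ± 0.82 without passing the threshold (adjusted p = 0.0764), which it passed without CN 2 of day 16 (3.44), without the 5 arrays farthest from their group mean (2.93) and with array weights (3.18). DGAT2 lost its call without CN 1 of day 13 or CN 4 or CN 5 of day 16, and ITGB3 without CN 3 of day 16. Of the 16 cholesterol synthesis genes none passed over all probe sets and 6 rose when adjusted over the list alone (camera adjusted p = 1.32e-07, and adjusted p = 0.403 with an estimated correlation). In all, 160 probe sets changed, 68 upward and 92 downward. The count was 99 without CN 1 and 94 without CN 5 of day 13, 284 without the 5 arrays farthest from their group mean, 753 with array weights and 429 in PN heifers.

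**Figure D1:**
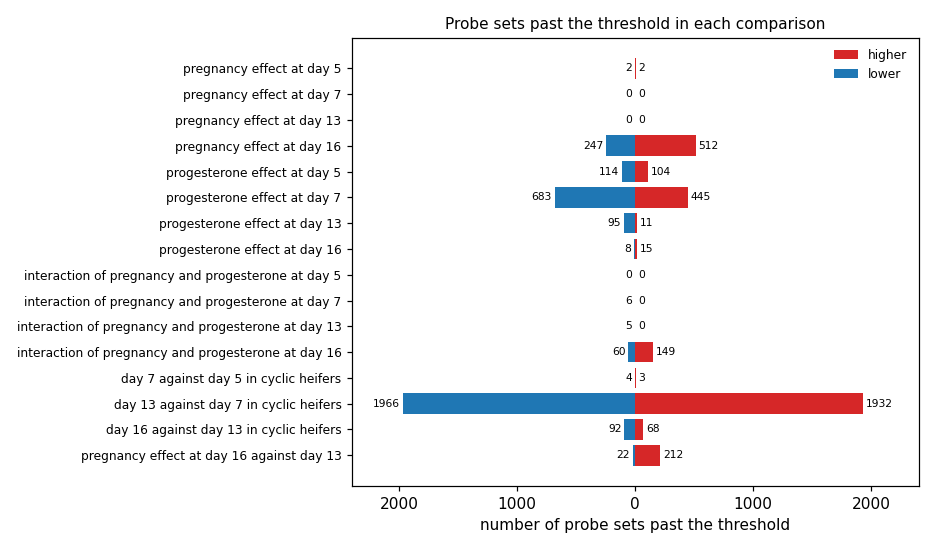
Number of probe sets past the threshold in each of the 16 comparisons, with those higher drawn to the right and those lower to the left of 0. The change from day 7 to day 13 of the cycle holds 1932 higher and 1966 lower probe sets, and the pregnancy effect at day 16 holds 512 and 247.

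The effect of pregnancy was asked on each day as pregnant minus cyclic, averaged over both progesterone levels. On day 16 (n = 10 pregnant and 10 cyclic) the 8 largest rises among named genes all belonged to the interferon-stimulated genes, which serve antiviral defence. MX2 (gene ID 280873), a dynamin-like GTPase, rose by 7.03 ± 0.70 (adjusted p = 1.31e-11), from 2.06 ± 0.00 in CN and 2.25 ± 0.27 in CH to 9.01 ± 0.82 in PN and 9.35 ± 2.48 in PH. With both cyclic groups near the floor, this difference is a lower limit. Among PH arrays PH 5 stood lowest in MX2, at 5.06 against 9.46 to 11.22 in the others. RSAD2, the antiviral protein viperin, rose by 6.24 ± 0.70, ISG15 (gene ID 281871), a ubiquitin-like modifier, by 6.20 ± 0.77, IFI44 by 5.17 ± 0.57, USP18, the protease that removes ISG15, by 4.35 ± 0.52 and MX1 by 3.82 ± 0.60. For MX2, RSAD2, ISG15 and IFI44 all 10 pregnant arrays lay above all 10 cyclic arrays. Of the 41 measured interferon-stimulated genes 37 rose and 1 fell, with the same counts adjusted over the list alone, and the median difference was 2.87. The member that fell was HERC5, a ligase for ISG15, at -0.77, named here after its values were seen. The list mean lay between 7.76, in PH 5, and 10.19 in pregnant arrays and between 6.04 and 6.44 in cyclic arrays. Its camera adjusted p was 7.15e-111, and the call held with an estimated correlation (adjusted p = 1.88e-05). This list too was drawn partly from published work on these animals and is not independent evidence of its direction.

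**Figure D2:**
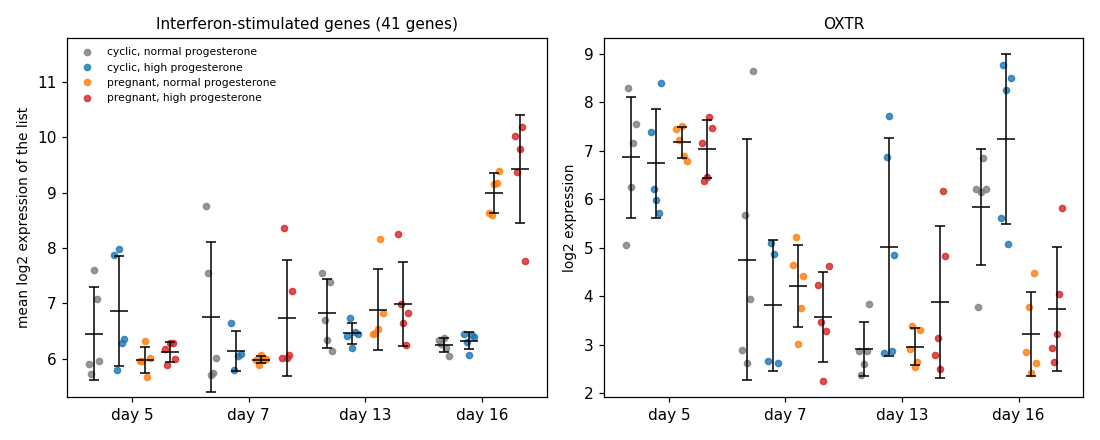
Mean log2 expression of the 41 interferon-stimulated genes (left) and log2 expression of OXTR (right) in each array, by day and group, with 1 point per array and bars for the group mean ± SD. On day 16 the list lies between 7.76 and 10.19 in pregnant arrays and between 6.04 and 6.44 in cyclic arrays, and OXTR differed by -3.06 ± 0.58 between pregnant and cyclic heifers.

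Genes of antigen processing rose with pregnancy on day 16, 7 of 15 (10 adjusted over the list alone), among them the peptide transporter TAP1 at 1.33 ± 0.24 and the immunoproteasome subunits PSMB8 at 0.81 ± 0.22 and PSMB9 at 0.76 ± 0.21. That call also held with an estimated correlation (adjusted p = 0.0306). Of 23 complement and acute phase genes 6 rose, also when adjusted over the list alone, with C4A at 1.69 ± 0.29, and the complement C1q chains C1QC at 1.41 ± 0.34 and C1QB at 1.23 ± 0.31 (camera adjusted p = 0.00401, and adjusted p = 0.607 with an estimated correlation). Both C1q chains are also macrophage markers, of which 3 of 16 rose (5 adjusted over the list alone; adjusted p = 0.769 with an estimated correlation), the third being the Fc receptor chain FCER1G at 0.87 ± 0.26. The chemokine CCL8 rose by 3.44 ± 0.51, the B cell factor TNFSF13B by 1.46 ± 0.28 and IL15, a growth factor of natural killer cells, by 0.82 ± 0.19. Of the 41 histotroph genes 5 rose (10 rose and 2 fell adjusted over the list alone; adjusted p = 0.175 with an estimated correlation). Among them were PLET1, a surface protein of epithelium and placenta, at 3.40 ± 0.55, DKK1 at 2.44 ± 0.48 and LGALS9, a galectin, at 1.98 ± 0.30, a member of the interferon list as well. Over the 20 omissions of 1 array FCER1G lost its call in 15, PSMB9 in 7 and PSMB8 in 5.

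OXTR was lower by 3.06 ± 0.58 in pregnant than in cyclic heifers on day 16 (adjusted p = 0.000204). It stood at 5.84 ± 1.19 in CN and 7.24 ± 1.76 in CH, against 3.23 ± 0.87 in PN and 3.73 ± 1.28 in PH. PGR and ESR1, the receptors of progesterone and estradiol, differed by -0.07 ± 0.21 and -0.15 ± 0.15, at mean levels of 2.78 and 2.5 near the floor, where a change is hard to see. Endothelial genes moved downward, 3 of 14 and as many adjusted over the list alone, with PECAM1 at -0.70 ± 0.19, the VEGF receptor FLT1 at -0.65 ± 0.13 and TIE1 at -0.39 ± 0.10 (camera adjusted p = 0.00401, and adjusted p = 0.607 with an estimated correlation). The group means of the list were 6.0 ± 0.32 in CN, 6.01 ± 0.38 in CH, 5.78 ± 0.19 in PN and 5.75 ± 0.22 in PH. The 10 smooth muscle markers were lower too, at 7.54 ± 0.52, 7.90 ± 0.34, 7.18 ± 0.31 and 7.25 ± 0.67, but none passed over all probe sets or adjusted over the list alone (median -0.44, camera adjusted p = 0.136, and adjusted p = 0.769 with an estimated correlation). CD93, a receptor of endothelial cells, changed by -1.27 ± 0.29 and SOX18, an endothelial transcription factor, by -1.0 ± 0.27. Of 40 extracellular matrix genes 3 fell, also when adjusted over the list alone (adjusted p = 0.769 with an estimated correlation), with COL15A1 at -0.75 ± 0.19, COL1A2 at -0.40 ± 0.09 and COL3A1 at -0.38 ± 0.08. SOX18 lost its call in 6 of the 20 omissions of 1 array, PECAM1 without PN 4 or PH 4 and TIE1 without CN 5. In all, 759 probe sets changed on day 16, 512 upward and 247 downward, and 212 and 19 of these changed at least 2-fold. The count was 158 (146 higher) at normal and 1868 (1039 higher) at high progesterone, with 126 higher probe sets shared against 6.32 under independence. Of the lower ones, 12 and 829, 1 was shared against 0.414, and 53.6% of the 829 had the same sign at normal progesterone. Without the arrays of narrow distribution, which belong to other days, the balance at high progesterone turned to 1303 higher and 2077 lower. The count was 374 in a fit of day 16 alone, 488 without PH 4, 1273 without PH 5, and 3663 with array weights, of which 2337 were lower.

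Before day 16 few probe sets passed the threshold for pregnancy. On day 5 (n = 10 each) 4 did, with 2370 at an unadjusted p under 0.05 against 1201 by chance. Among the 4 were those of ESR1 at 0.77 ± 0.15, CLN8, a membrane protein of the endoplasmic reticulum, at 0.52 ± 0.10 and CCNE1, a cyclin of the start of DNA synthesis, at -0.35 ± 0.07 (adjusted p = 0.041 for each). All lay at mean levels of 2.58 or less near the floor. ESR1 and CLN8 lost their calls in 11 and CCNE1 in 15 of the 20 omissions of 1 array. On day 7 (n = 10 pregnant and 9 cyclic) and on day 13 (n = 10 each) limma called 0 probe sets, with 1878 and 620 at an unadjusted p under 0.05. ISG15 differed by -1.21 ± 0.77, -0.05 ± 0.80 and 1.04 ± 0.77 on days 5, 7 and 13, and none of these passed the threshold. Leukocyte markers were lower in pregnant heifers on day 5 by camera, such as the 16 macrophage markers (median -0.39, adjusted p = 7.11e-08, and adjusted p = 0.315 with an estimated correlation). There CH 3 stood apart with B and plasma cell markers at 7.92 against 4.42 to 4.60 in the other CH arrays. The interferon list was lower too (median -0.58, adjusted p = 0.315 with an estimated correlation), and none of its 41 genes passed. There CN 3, CN 4, CH 1 and CH 3 stood apart at 7.60, 7.08, 7.87 and 7.98. The other cyclic arrays lay between 5.73 and 6.35 and the pregnant ones between 5.67 and 6.32. On day 13 that list was higher by camera, in 36 of 41 genes (median 0.22, adjusted p = 9.77e-06, and adjusted p = 0.989 with an estimated correlation), none of which passed. There PN 4 and PH 1 stood apart at 8.16 and 8.26, against 6.25 to 6.98 in the other pregnant arrays and 6.14 to 7.54 in cyclic arrays, and PH 1 has a narrow distribution. On day 7 the list did not differ by camera (median -0.10, adjusted p = 0.234). Smooth muscle markers, which belong to the muscle layer under the endometrium, were higher on day 13 (median 0.67, camera adjusted p = 7.55e-08, and adjusted p = 0.855 with an estimated correlation), with PH 4 at 12.27 against 6.93 to 7.98 in the other PH arrays. On day 5 the count ran from 0 to 16 over the omissions of 1 array and stayed within 1.5 times only without CN 3, CH 2, CH 5, PN 1 or PN 4. It was 0 in a fit of day 5 alone, with median centring, with a replicate block and among the brighter probe sets, and 16 with array weights. On day 7 it was 23 without CH 2, 20 without CH 5, 11 without CH 4, 2 without CH 3 and 1 without CN 4, PN 4 or PH 2, 75 at high progesterone and 42 with array weights. On day 13 it was 1 without CH 2 and 15 with array weights.

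The growth of the pregnancy effect from day 13 to day 16 was tested as a difference of differences (n = 10 per status and day). MX2 gained 6.50 ± 0.99, RSAD2 5.40 ± 0.99, IFIT2, an inhibitor of translation, 3.88 ± 0.61 and C4A 1.74 ± 0.41. Of the interferon list 35 of 41 genes rose and none fell (37 rose and 1 fell adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.000371). FGF10, a stromal growth factor, gained 1.23 ± 0.31. COL15A1 lost ground at -1.08 ± 0.27, FLT1 at -0.76 ± 0.18 and ACTA2, smooth muscle actin, at -2.50 ± 0.65. The 10 smooth muscle markers had a median of -1.14 (adjusted p = 0.463 with an estimated correlation), with 1 that fell and 2 adjusted over the list alone. Over the 40 omissions of 1 array ACTA2 lost its call in 11, FGF10 in 4 and COL15A1 in 3, each of them among others without PH 4 of day 13. In all, 234 probe sets differed, 212 upward and 22 downward. The count was 379 without PH 5 of day 16 and 685 with array weights.

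The effect of high progesterone was asked on each day as high minus normal, averaged over cyclic and pregnant heifers. On day 5 (n = 10 each) DGAT2 rose by 2.91 ± 0.44 (adjusted p = 1.77e-05), from 3.70 ± 1.57 to 6.64 ± 0.82 in cyclic and from 3.29 ± 0.56 to 6.16 ± 1.07 in pregnant heifers. MSTN, the growth inhibitor myostatin, rose by 2.75 ± 0.53, SSLP1, a secreted protein of the Ly-6 family, by 2.75 ± 0.53, SLC27A6, a fatty acid transporter, by 2.19 ± 0.50 and AREG, a ligand of the EGF receptor, by 1.54 ± 0.31. TIPARP (gene ID 540975), a poly(ADP-ribose) polymerase, fell by 1.54 ± 0.22 (adjusted p = 9.6e-06), and all arrays with high progesterone lay below all with normal progesterone. DKK1 changed by -2.17 ± 0.48, NMB, the peptide neuromedin B, by -2.17 ± 0.47, COL27A1, a collagen, by -1.19 ± 0.26 and FKBP4, a co-chaperone of steroid receptors, by -0.65 ± 0.14. Of the 41 histotroph genes, a list that is not independent of these animals, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0677). Macrophage markers were higher by camera (median 0.48, adjusted p = 1.02e-06, and adjusted p = 0.441 with an estimated correlation), with none of the 16 past the threshold and 2 adjusted over the list alone. There CH 3 stood highest, at 8.41 in the mean of these markers against 5.13 to 6.32 in the other CH arrays. The group means were 5.53 ± 0.37 in CN, 6.24 ± 1.29 in CH, 5.28 ± 0.38 in PN and 5.62 ± 0.18 in PH. In all, 218 probe sets changed, 104 upward and 114 downward. The count was 389 without CN 1, 141 without PN 2, 329 without the 5 arrays farthest from their group mean, 115 in a fit of day 5 alone, 600 with array weights, and 36 within cyclic and 36 within pregnant heifers.

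On day 7 (n = 10 normal and 9 high) DGAT2 again rose, by 3.09 ± 0.45 (adjusted p = 4.54e-06), and all arrays with high progesterone lay above all with normal progesterone. Among CN arrays DGAT2 was lowest in CN 5, at 3.10 against 4.94 to 7.01 in the others, which enlarges this difference. HPSE, the heparan sulfate degrading enzyme heparanase, rose by 2.27 ± 0.28, ASGR2, a glycoprotein receptor, by 2.61 ± 0.38, HAVCR1, a phosphatidylserine receptor, by 2.16 ± 0.27 and ACACA, the first enzyme of fatty acid synthesis, by 1.15 ± 0.23. FABP3 (gene ID 281758), a fatty acid binding protein, fell by 3.19 ± 0.51 (adjusted p = 2.31e-05), from 7.81 ± 1.59 to 4.78 ± 0.59 in cyclic and from 8.01 ± 1.37 to 4.66 ± 1.43 in pregnant heifers. SLC6A20, an amino acid transporter, changed by -2.37 ± 0.52 and PLAU, the plasminogen activator urokinase, by -1.13 ± 0.25. MSTN and DKK1 differed by 0.05 ± 0.54 and -0.98 ± 0.50 on this day and did not pass.

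Cell cycle genes fell with high progesterone on day 7, 22 of 38 with none that rose (28 adjusted over the list alone). BIRC5 changed by -2.20 ± 0.44, UBE2C by -2.20 ± 0.44, RRM2, a subunit of ribonucleotide reductase, by -2.15 ± 0.44, and CDK1, the kinase of mitotic entry, by -2.04 ± 0.42. For BIRC5 this SE borrows from arrays at the floor, where it lay between 2.34 and 2.55 on days 13 and 16. In CN of day 7 it ran from 2.53 to 7.94, so the SE can be too small. The mean of the list was 5.99 ± 1.09 in CN and 4.57 ± 0.29 in CH, and 5.56 ± 0.71 in PN and 4.88 ± 0.52 in PH. Its camera adjusted p was 4.38e-19, and adjusted p = 0.263 with an estimated correlation. Macrophage markers were lower as well, from 5.47 ± 0.64 in CN to 4.74 ± 0.08 in CH and from 5.18 ± 0.42 in PN to 4.92 ± 0.29 in PH. None of the 16 passed and 3 fell adjusted over the list alone (median -0.46, camera adjusted p = 0.0191, and adjusted p = 0.908 with an estimated correlation). CN 5 was the highest array of its group in both lists, at 7.00 in cell cycle genes and 6.41 in macrophage markers. Of 16 cholesterol synthesis genes 3 rose, also when adjusted over the list alone, HMGCS1 at 0.74 ± 0.19, FDPS at 0.58 ± 0.17 and CYP51A1 at 0.56 ± 0.17 (camera adjusted p = 0.000198, and adjusted p = 0.893 with an estimated correlation). Among the 41 histotroph genes, not independent of these animals, 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.561), with PENK, an opioid peptide precursor, at 1.07 ± 0.31 and TIMP2, a metalloprotease inhibitor, at 0.70 ± 0.14. Over the 19 omissions of 1 array CYP51A1 lost its call in 14, FDPS in 8 and PENK in 8, and PENK stood at 0.69 without CN 5. In all, 1128 probe sets changed, 445 upward and 683 downward, with a balance that turned to 614 upward and 579 downward after quantile normalization. The count was 223 in a fit of day 7 alone, 730 without the 5 arrays farthest from their group mean, and 126 within pregnant heifers. Within cyclic heifers it was 908, and 199 without the arrays of narrow distribution, of which CH 3 belongs to this day.

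**Figure D3:**
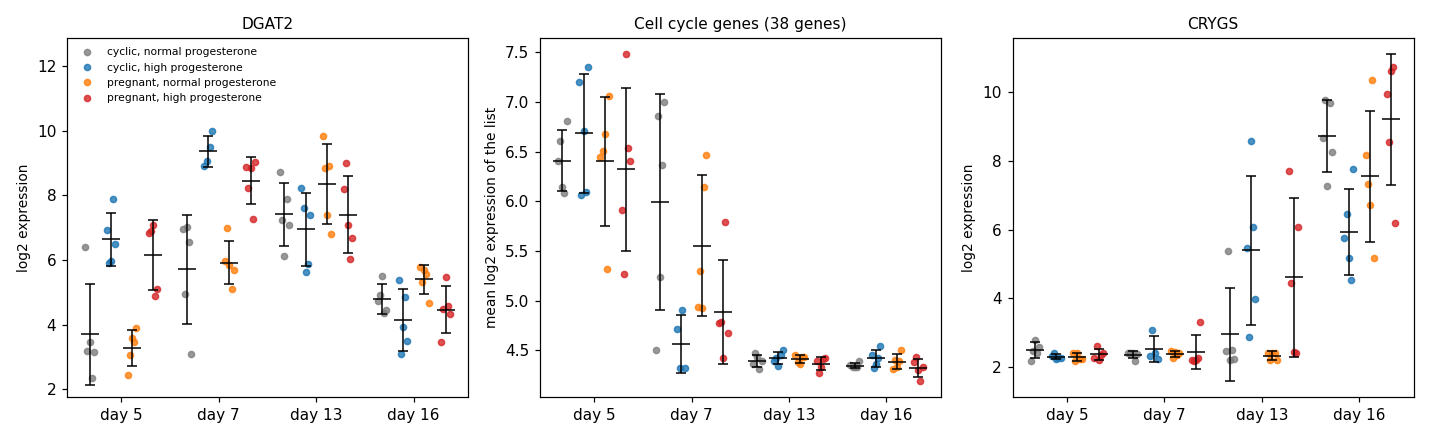
Log2 expression of DGAT2 (left), mean log2 expression of the 38 cell cycle genes (middle) and log2 expression of CRYGS (right) in each array, by day and group, with 1 point per array and bars for the group mean ± SD. DGAT2 rose with high progesterone by 2.91 ± 0.44 on day 5 and 3.09 ± 0.45 on day 7, the cell cycle mean on day 7 was 5.99 in CN and 4.57 in CH, and CRYGS on day 16 was 8.74 in CN, 5.93 in CH, 7.56 in PN and 9.22 in PH.

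On day 13 (n = 10 each) high progesterone went mainly with lower values. MRPS36 (gene ID 613835), a protein named for the mitochondrial ribosome, fell by 1.49 ± 0.19 (adjusted p = 2.92e-07), from 12.05 ± 0.60 to 10.50 ± 0.92 in cyclic and from 12.08 ± 0.13 to 10.63 ± 0.68 in pregnant heifers. CPN1, a carboxypeptidase subunit, changed by -2.08 ± 0.39, GJB5, a connexin, by -2.0 ± 0.38, PHGDH, the first enzyme of serine synthesis, by -1.71 ± 0.33, and MTHFD1L, an enzyme of mitochondrial folate metabolism, by -1.68 ± 0.30. CRYGS rose by 2.37 ± 0.53, CA2, a carbonic anhydrase, by 2.11 ± 0.53 and FAM167A by 1.18 ± 0.26. Of the 38 cell cycle genes 2 fell, the probe set named for the mitotic cyclin CCNB1 at -1.62 ± 0.30 and the thymidine kinase TK1 at -0.84 ± 0.20. CRYGS, FAM167A and TK1 lost their calls without CH 3 or PH 1, TK1 also without PN 2, and CA2 in 13 of the 20 omissions of 1 array. The probe set of CCNB1 stood at 11.08 ± 0.47 in CN while the mean of its list was 4.39 ± 0.06. Levels of different probe sets are not comparable, so the level alone does not decide whether the probe set measures CCNB1. Its course differed from that of the list. In CN it ran from 10.58 to 11.86 on day 5 and from 10.27 to 11.46 on day 13. The list mean ran from 6.08 to 6.81 and from 4.31 to 4.47 on these days. In CN these values argue against the probe set as a marker of the cell cycle. Whether it measures CCNB1 was not tested. DGAT2, MSTN and DKK1 differed by -0.71 ± 0.44, 0.31 ± 0.53 and -0.98 ± 0.48 and did not pass. In all, 106 probe sets changed, 11 upward and 95 downward. The count was 181 without CH 1, 60 without CH 3, 160 without PH 4, 174 without the 3 arrays highest in smooth muscle markers, 167 without the 5 arrays farthest from their group mean, 31 in a fit of day 13 alone, 413 with array weights, and 15 within pregnant heifers.

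On day 16 (n = 10 each) RNF144B, a ubiquitin ligase, rose with high progesterone by 1.27 ± 0.24 (adjusted p = 0.00863), from 8.13 ± 0.44 to 9.19 ± 0.48 in cyclic and from 7.80 ± 0.55 to 9.28 ± 0.47 in pregnant heifers. KRT17, a keratin, rose by 1.27 ± 0.23 at a mean level of 2.64, and HNF4G, a nuclear receptor, by 0.56 ± 0.10. The same probe set of CCNB1 changed by -1.36 ± 0.30 (adjusted p = 0.0325) and lost its call in 7 of the 20 omissions of 1 array. OXTR differed by 0.95 ± 0.58 and did not pass. In all, 23 probe sets changed, 15 upward and 8 downward. The count was 13 without CN 3, 5 without CN 5, 119 without CH 1, 198 without CH 2, 6 without CH 3, 11 without PN 1, 8 without PN 2, 35 without PN 4, 8 without PH 1 and 115 without PH 5. It was 0 in a fit of day 16 alone, 13 after quantile normalization, 2 among the brighter probe sets, 5740 with array weights and 701 within cyclic heifers. Of these 701, 313 were higher and 388 lower, and 44.4% and 35.3% had the same sign in pregnant heifers. None was shared with the 18 higher and 7 lower calls in pregnant heifers, but independence gives only 0.235 and 0.113, so this decides nothing. The averaged count was 1704 without the arrays of narrow distribution on other days, which enter through the shared spread. The cyclic one then turned to 3989 higher and 1017 lower, of which 81.3% and 40.1% had the same sign in pregnant heifers. Averaged, it was 1765 without the 5 arrays farthest from their group mean.

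Whether progesterone acted differently with pregnancy was tested as an interaction, the progesterone difference in pregnant minus that in cyclic heifers. On day 16 (n = 5 per group) CRYGS had an interaction of 4.46 ± 1.05, with 8.74 ± 1.05 in CN, 5.93 ± 1.25 in CH, 7.56 ± 1.91 in PN and 9.22 ± 1.90 in PH. GSTA2, a glutathione transferase, stood at 3.05 ± 0.76, DEPP1, a regulator of autophagy, at 2.22 ± 0.37, PIK3IP1, an inhibitor of phosphoinositide 3-kinase, at 1.91 ± 0.39 and PGRMC1, a membrane component of progesterone binding, at 0.94 ± 0.20. ADAMTS4, an aggrecan-degrading protease, had -2.53 ± 0.66, ACKR1, a chemokine-binding receptor of venules, -2.06 ± 0.41 and EDNRB, an endothelin receptor, -2.06 ± 0.41. All 3 had their highest group mean in CH, at 6.21 ± 1.94, 4.94 ± 1.31 and 3.89 ± 1.49. Without CH 3 all of these genes except DEPP1 lost their calls, at adjusted p of 0.0596 to 0.155. Their interactions were then 4.27 for CRYGS, 3.18 for GSTA2, 1.58 for PIK3IP1, 0.89 for PGRMC1, -1.97 for ADAMTS4, -1.84 for ACKR1 and -1.69 for EDNRB. Over the 20 omissions of 1 array ADAMTS4 lost its call in 10, GSTA2 in 9 and CRYGS in 8. CH 3 and CH 1 were also the highest of day 16 in the mean of the immediate early and heat shock genes, at 10.15 and 9.90, with group means of 9.46 ± 0.57 in CH, 9.09 ± 0.11 in CN, 9.21 ± 0.09 in PN and 9.32 ± 0.25 in PH, a measure looked at after the interaction was seen. The interaction of that list had a median of -0.17 (camera adjusted p = 0.125). ISG15 did not differ by the test, at -0.19 ± 1.54, and stood at 0.31 without PH 5 (limma adjusted p = 0.954). In all, 209 probe sets passed, 149 upward and 60 downward. The count was 671 without CH 2, 568 without CH 1, 395 without PH 5, 384 without PN 1, 95 without PH 1, 91 without PH 3, and 83 without CH 5 or PN 5. It was 79 without PH 4, 77 without CN 5, 75 without CH 4, 41 without CN 2, 23 without PN 3 and 3 without CH 3. It was 9 in a fit of day 16 alone, 351 without the arrays of narrow distribution, 518 without the 5 arrays farthest from their group mean and 3291 with array weights.

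On the earlier days few interactions passed. On day 5 (n = 5 per group) limma called 0 probe sets, with 686 at an unadjusted p under 0.05, and 1 without PN 4, PH 3, PH 4 or PH 5 and with array weights. On day 7 (n = 4 in CH and 5 elsewhere) 6 passed, with 4658 at an unadjusted p under 0.05 against 1201 by chance. All 6 were lower, among them HBB, a hemoglobin chain, at -0.47 ± 0.10 and TEPSIN, a protein of vesicle coats, at -0.17 ± 0.04, both under a mean level of 3. Each lost its call in 15 of the 19 omissions of 1 array, and HBB stood at -0.30 without CH 3. Of the 6 red blood cell markers HBB was the 1 that fell (4 adjusted over the list alone; adjusted p = 0.337 with an estimated correlation). On day 13 (n = 5 per group) 5 passed, with 2413 at an unadjusted p under 0.05. All 5 were lower, and the named ones were CREM, a cAMP-responsive transcription factor, at -1.83 ± 0.35 and BRD8, a bromodomain protein, at -1.51 ± 0.29. They lost their calls in 9 and 8 of the 20 omissions of 1 array. CREM, BRD8 and TEPSIN were chosen after their values were seen, each by a probe set other than the brightest of its gene. The day 7 count was 3210 without CH 5, 2476 without CH 2, 52 without CH 4 and 12 without PN 5. It was 1 to 3 without any array of CN, PN or PH other than CN 3, PN 4 and PN 5. With array weights it was 43, and it was 0 in a fit of day 7 alone and among the brighter probe sets. The day 13 count was 0 without CN 1, CN 2, CH 1, CH 3, PN 1 or PH 5, 1 without CN 4, 2 without CN 3, 3 without PN 3 or PH 1, 8 without PN 5, 9 without PH 3 and 10 without CN 5. A fit of day 13 alone gave 140, array weights 1542 and the brighter probe sets 0.

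**Figure D4:**
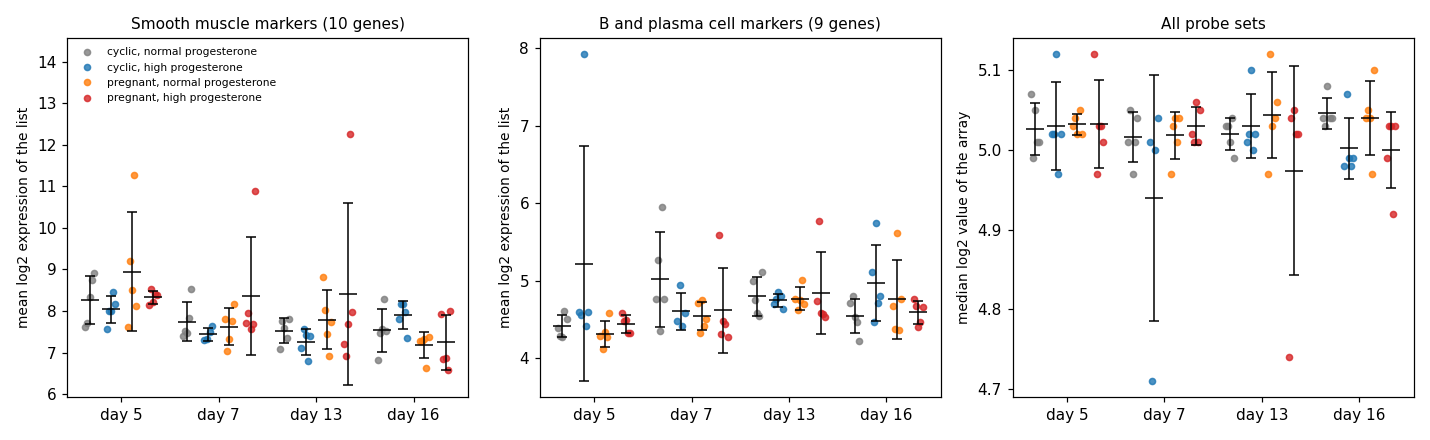
Mean log2 expression of 10 smooth muscle markers (left), of 9 B and plasma cell markers (middle) and median log2 value over all probe sets (right) in each array, by day and group, with 1 point per array and bars for the group mean ± SD. Single arrays stand apart, such as PH 4 of day 13 at 12.27 in smooth muscle markers, CH 3 of day 5 at 7.92 in B and plasma cell markers, and CH 3 of day 7 with a median of 4.71.

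Whether high progesterone moved the endometrium ahead along the cycle was asked by setting, across probe sets, the progesterone difference in pregnant heifers against the change to the next day studied in CN heifers. Across the 3898 probe sets that changed from day 7 to day 13, the day 7 difference between PH and PN had a Spearman correlation of 0.701 with that change (exact permutation p = 0.0159, adjusted p = 0.0357 over 3 tests). The test was two-sided over all relabellings of the 5 PN and 5 PH arrays, and 83.3% had the same sign. DGAT2 was higher and the cell cycle genes BIRC5 and UBE2C were lower in both comparisons. Other genes of that course did not move this way. IGFBP1 stayed near the floor on day 7, at 2.89 to 2.96 in PN and 2.23 to 3.32 in PH. DKK1, which rose over those days, ran from 6.63 to 8.31 in PN and from 4.28 to 8.38 in PH. The 8 genes that rose most averaged at most 5.52 in any array of days 5 and 7, against at least 8.30 on days 13 and 16. Across the 160 probe sets that changed from day 13 to day 16 the correlation of the day 13 difference was 0.868 (exact permutation p = 0.0238, adjusted p = 0.0357), with 81.9% of the same sign. CRYGS, CA2, CPN1, PDZK1IP1 and GJB5 moved the same way in both. Across the 7 probe sets that changed from day 5 to day 7 it was 0.0357 (exact permutation p = 0.937). Probe sets are not independent replicates, and the smallest p that these relabellings can give is 0.00794. With the progesterone difference of cyclic heifers against the course of PN heifers, day 7 gave 0.512 (exact permutation, adjusted p = 0.167) and day 13 gave 0.504 (exact permutation, adjusted p = 0.619). Day 13 did not pass over all probe sets (0.151; exact permutation, adjusted p = 0.246), by the share of the same sign (exact permutation, adjusted p = 0.226) or without PN 2, PN 3 or PH 2 (exact permutation, adjusted p = 0.0596 for each).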

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

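Tests of swapped or mixed RNA, of a conceptus before day 16, of the narrow array, of array CN 5 of day 7 and of courses or responses that depend on pregnancy were chosen only after the result was seen.

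In 128 checks of a group for an array far from the others, over 8 measures, 17 stood apart, where chance gives about 1 in 20, or 6.4. In smooth muscle markers PH 5 of day 7 stood at 10.89 (others 7.58 to 7.96), PH 4 of day 13 at 12.27 (6.93 to 7.98) and PN 4 of day 16 low at 6.64 (7.27 to 7.38). On day 5 CH 3 was high in T and NK cell markers at 4.94 (3.01 to 3.30), in B and plasma cell markers at 7.92 (4.42 to 4.60) and in neutrophil markers at 6.72 (2.38 to 2.61). B and plasma cell markers also stood out in PH 1 of day 7 at 5.59 (4.28 to 4.48) and in PH 2 of day 13 at 5.77 (4.53 to 4.74). Neutrophil markers did in CN 5 of day 7 at 2.90 (2.27 to 2.37). Macrophage markers were high in CH 4 of day 13 at 5.73 (4.84 to 4.99) and low in PN 2 of day 16 at 5.10 (5.27 to 5.33). Cell cycle genes were high in PH 4 of day 7 at 5.79 (4.42 to 4.78). The array median was low in CH 3 of day 7 at 4.71 (5.00 to 5.04) and in PH 1 of day 13 at 4.74 (5.02 to 5.05). It was high in CH 3 of day 13 at 5.10 (5.00 to 5.02) and in CH 2 of day 16 at 5.07 (4.98 to 4.99).

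Differences between effects passed the threshold for 6 probe sets on day 7, 5 on day 13 and 209 on day 16 in the interaction of pregnancy with progesterone. Between day 16 and day 13 the pregnancy effect differed for 234.

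Interferon-stimulated genes were high in single arrays before day 16, such as PN 4 of day 13 at 8.16 (6.45 to 6.83 in the others), with 8 of 29 cyclic and 4 of 30 pregnant arrays over 7. On days 5 and 7 together the values argue against a conceptus, with pregnant minus cyclic at -0.34 ± 0.25 (permutation p = 0.198). This rests on day 5 at -0.60 ± 0.30 (permutation p = 0.0679), and day 7 alone, at -0.09 ± 0.39 (permutation p = 0.843), leaves it open. On both days the values also argue against RNA of a pregnant day 16 sample. The 8 genes that rise most from day 7 to day 13 averaged at most 5.52 there and at least 8.30 on days 13 and 16, a gap of 2.78. On day 13 the difference was 0.31 ± 0.28 (permutation p = 0.294), so a conceptus stays open for pregnant arrays of that day, though cyclic arrays before day 16 reached 8.76. Leukocytes may contribute, by deviations from group means over 59 arrays. The list rose with leukocyte markers at a Spearman correlation of 0.331 (permutation p = 0.0251) and a Pearson correlation of 0.301 (permutation p = 0.0814). Without the arrays highest in the markers, CH 3 of day 5 and CN 5 of day 7, these were 0.361 (permutation p = 0.0166) and 0.266 (permutation p = 0.0492). Without those farthest from the median, CH 3 and CH 2 of day 5, they were 0.265 (permutation p = 0.0636) and 0.129 (permutation p = 0.419), so the p rests on those samples. Group means were not recomputed for these omissions. Of the arrays highest in the markers, CH 3 of day 5 had a list mean of 7.98 and CN 5 of day 7 one of 6.02. CN 1 and PH 2 of day 7, with list means of 8.76 and 8.36, were not the highest of their groups in any leukocyte list. Of the 54 leukocyte markers 16 lay above the median probe set level (the brightest being BLNK at 9.14, C1QA at 9.09 and PRDM1 at 8.48) and 3 belong to other lists, and neither mixing on day 13 nor an exposure of single animals was tested.

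On day 7 high progesterone went with 908 probe sets in cyclic and 126 in pregnant heifers, and of the 471 that were higher in cyclic heifers 46.9% had the same sign in pregnant heifers. Array CH 3, with its narrow distribution, is a candidate source, since without the narrow arrays the cyclic count was 199 and the share 82.8%. PH 1 of day 13 was left out with it and enters through the shared spread, so this count and share do not belong to CH 3 alone. The omission of CH 3 alone is given only for the averaged effect and the interaction. There HBB lost its interaction call, at -0.30 (limma adjusted p = 0.277). A response that depends on pregnancy cannot be told apart from no difference, because without those arrays the interaction passed for 8 probe sets, with 1260 at an unadjusted p under 0.05 against 1201 by chance, a small excess that decides neither way. With all arrays the interaction passed for 6 probe sets, with 4658 at an unadjusted p under 0.05. What made the distribution of CH 3 narrow was not tested.

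From day 5 to day 7 limma called 1155 probe sets in PN and 7 in CN heifers. Without CN 5 of day 7 the CN count was 596, calls shared in sign rose from 1 to 219, and the share of the PN changes with the same sign in CN heifers went from 86.8% to 92.4%, so this array may hide much of the course. A course that depends on pregnancy stays open: the difference of courses passed for 0 probe sets, with 1664 at an unadjusted p under 0.05 against 1201 by chance, and 1356 without CN 5. OXTR stood at 8.65 in CN 5 (2.63 to 5.67 in the other CN arrays of day 7), DGAT2 at 3.10 (4.94 to 7.01) and MSTN at 8.05 (2.57 to 4.03). BIRC5 at 6.86 (2.53 to 7.94) and SLC2A5 at 7.25 (4.63 to 9.38) lay within the others. CN 5 also enters the progesterone effect on day 7 and the course to day 13. Whether CN 5 was an animal of another stage was not tested.

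Other splits of the same arrays, 100 per comparison with the real one included, were set against each count. The smallest share they can give is 1 in 100, which is unadjusted over the 16 comparisons. At that share only, chance can be excluded for the pregnancy effect on day 16 (759 against 350 in the highest other split) and its difference from day 13 (234 against 10). The same holds for the progesterone effect on day 5 (218 against 20), day 7 (1128 against 115) and day 13 (106 against 26). It also holds for day 13 against day 7 (3898 against 1964) and day 16 against day 13 (160 against 28). In each of these 1 split, the real one, gave as many. For the interaction on day 13 (5 against 26, as many in 4 splits) and day 16 (209 against 619, as many in 2) the splits cannot decide. They moved arrays across all groups of the day, which also broke up the effects of pregnancy and progesterone, so they do not test the interaction alone. These shares are unadjusted over the 16 comparisons, and the highest other split gave more. Both counts also hang on single arrays (0 on day 13 without CH 3, among others, and 3 on day 16 without CH 3). Chance cannot be excluded for the pregnancy effect on day 5 (4 against 60, as many in 12 splits), the progesterone effect on day 16 (23 against 74, 6 splits), the interaction on day 7 (6 against 190, 18 splits) and day 7 against day 5 (7 against 2649, 25 splits). Where the real count was 0, for the pregnancy effect on day 7 (highest other 44) and day 13 (3) and the interaction on day 5 (14), the splits decide nothing, since any split gives as many and all 100 did. Splits with 2649, 74 and 60 called several times the real count, which may come from a structure of the samples beyond their groups, but this was not tested. Those with 619, 190 and 26 mixed the pregnancy and progesterone groups of a day. The effects of these factors can enter such splits, so they do not show a structure beyond the groups.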

How the results depend on the processing

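The omissions of arrays with a narrow distribution, far from their group mean or high in smooth muscle markers are tests chosen only after the result was seen. Low signal over background was a limit: 32.2% of probe sets had a mean under 3, where PGR and ESR1 lie and changes are compressed. Of 143 gene results 130 were past the threshold, of which 94 stayed so in every omission of 1 array and 36 did not; over the settings 1648 of 1879 values kept direction and side of the threshold, 214 lost the call, 3 gained it and 14 changed sign. The fit of the days concerned, which has fewer arrays, lost 56 of these calls and pregnant heifers alone lost 31. Of the 32 list results named in the text 21 were past the threshold by camera, and of these 21 held with the mean over the probe sets of a gene, 8 by fry and 3 with an estimated correlation. For the cell cycle list under progesterone on day 13, not past the threshold, fry gave the opposite direction (adjusted p = 0.988). Scalings moved the median change by -0.086 to 0.08. For the counts below the cause of a move was not tested, also where fewer arrays or probe sets entered.

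The fit of the days concerned gave 0 for pregnancy on day 5 and 374 on day 16, 115, 223, 31 and 0 for progesterone on days 5, 7, 13 and 16, 0, 140 and 9 for the interaction on days 7, 13 and 16, and 1 for day 7 against day 5, with 6 other counts within 1.5 times. Quantile normalization gave 13 for progesterone on day 16 and 2 for the interaction on day 13, and 14 others stayed within 1.5 times. Median centring gave 0 and 3 for pregnancy on days 5 and 7 and 3 for the interaction on day 7. Brighter probe sets gave 0 for pregnancy on day 5, 2 for progesterone on day 16, 0 and 0 for the interaction on days 7 and 13 and 0 for day 7 against day 5. Trend and robust moderation gave 1 for pregnancy and 3 for the interaction on day 7. The replicate block gave 0 for pregnancy on day 5 and 4 for day 7 against day 5.

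Array weights raised nearly all counts: to 16, 42, 15 and 3663 for pregnancy on days 5, 7, 13 and 16, 600, 413 and 5740 for progesterone on days 5, 13 and 16, 1, 43, 1542 and 3291 for the interaction on days 5, 7, 13 and 16, 1386 for day 7 against day 5, 753 for day 16 against day 13 and 685 for the change of the pregnancy effect. Single arms have fewer arrays. At high progesterone pregnancy gave 2, 75, 1 and 1868 on days 5, 7, 13 and 16, and at normal progesterone 1 and 158 on days 13 and 16. In cyclic heifers progesterone gave 36 and 701 on days 5 and 16, and in pregnant heifers 36, 126 and 15 on days 5, 7 and 13. PN heifers gave 1155 for day 7 against day 5 and 429 for day 16 against day 13.

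Without both narrow arrays the counts were 2 and 1 for pregnancy on days 7 and 13, 1704 for progesterone on day 16, and 3 and 351 for the interaction on days 13 and 16. Without the 5 far arrays they were 3 and 3 for pregnancy on days 7 and 13, 329, 730, 167 and 1765 for progesterone on days 5, 7, 13 and 16, 518 for the interaction on day 16, 881 for day 7 against day 5 and 284 for day 16 against day 13. Without the 3 arrays high in smooth muscle markers they were 174 for progesterone on day 13 and 1 for the interaction on day 7.

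Over the omissions of 1 array the pregnancy counts ran from 0 to 16, 0 to 23, 0 to 1 and 488 to 1273 on days 5, 7, 13 and 16, and the progesterone counts from 141 to 389, 757 to 1467, 60 to 181 and 5 to 198. The interaction counts ran from 0 to 1, 1 to 3210, 0 to 10 and 3 to 671. Day 7 against day 5 ran from 1 to 596, day 13 against day 7 from 3229 to 3713, day 16 against day 13 from 94 to 195 and the change of the pregnancy effect from 184 to 379. The correlation for an advance ran from 0.0357 to 0.143 on day 5, 0.647 to 0.722 on day 7 and 0.840 to 0.888 on day 13. It lost the threshold on days 7 and 13 with cyclic heifers against the course of PN heifers (0.512 and 0.504; exact permutation, adjusted p = 0.167 and 0.619), and on day 13 over all probe sets (0.151; exact permutation, adjusted p = 0.246), by the share of the same sign (81.9%; exact permutation, adjusted p = 0.226) and without PN 2, PN 3 or PH 2 (0.856, 0.855 and 0.840; exact permutation, adjusted p = 0.0596 each).

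Changes of sign were seen only in gene values that had not passed the threshold. They were ISG15 for pregnancy on day 7 at high progesterone (1.61) and without 1 array (-0.53 to 0.55), ISG15 in the interaction on day 16 with array weights (0.25) and without 1 array (-0.41 to 0.31), and PGR for pregnancy on day 16 with array weights (0.074) and without 1 array (-0.12 to 0.034). For progesterone on day 7 MSTN reached -0.032 with array weights, -0.001 with the replicate block, -0.21 in cyclic heifers, -0.078 without the narrow arrays, -0.068 without the smooth muscle arrays and -0.14 to 0.55 without 1 array. In pregnant heifers on day 13 MSTN stood at -0.65 and DKK1 at 0.018.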

Other observations

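No test in this part was chosen after its result was seen.

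Metabolic genes went both ways from day 7 to day 13 of the cycle (n = 5 CN arrays per day). Of 21 genes of hypoxia and glycolysis 4 rose and 4 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.838). EPAS1, an oxygen-regulated transcription factor, rose by 1.39 ± 0.22 and SLC2A1 by 1.41 ± 0.27, whereas the brightest probe set of LDHA, lactate dehydrogenase, changed by -2.45 ± 0.22 and its other probe sets by -0.08 and 0.23. Of 16 cholesterol synthesis genes 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.674), with HMGCS1 at 1.24 ± 0.26, CYP51A1 at 1.15 ± 0.24 and SQLE at 1.10 ± 0.30. Of 23 complement genes 5 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.654), with clusterin, CLU, at 1.24 ± 0.15, the complement inhibitor CD55 at 1.21 ± 0.30 and C5 at -2.81 ± 0.70. MET, the receptor of hepatocyte growth factor, rose by 1.99 ± 0.29.

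On day 16 none of the 14 conceptus and trophoblast markers passed the threshold with pregnancy by limma or adjusted over the list alone, and their median difference was -0.02 (camera adjusted p = 0.475). The first component of the values held 36.7% of the variance, the second 8.02% and the third 5.7%.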
